A study of Junonia coenia with 24 samples.

How the data were processed

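The study assayed open chromatin by ATAC-seq, with hyperactive Tn5 transposase on nuclei of whole wing tissue, in 24 libraries of Junonia coenia, per the labels' protocols. The deposited values are read counts per peak interval, not normalized, made by the authors before deposit in a table for each wing with its own list of intervals. Bowtie2 and deepTools were used upstream, per the submitters' processing notes, which give neither versions nor roles. The genome build, the peak caller, read filters, the handling of duplicate reads, any shift of read ends for the transposase and whether libraries were pooled for peak calling are not given in the sources used here. Duplicated or multiply mapping reads left in the counts would lower their true precision, and interval edges set by the authors' peak calling decide which reads a count holds. Interval starts counted from 0 in the tables were converted to positions counted from 1.

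Libraries were assigned to 8 groups of wing and stage by the labelled tissue and developmental stage, with the replicate number of the title, and all table columns were mapped to a library by name. The labels number the replicates and do not say that they came from separate animals, so p-values measure only the spread between these samples, which may be technical. Tests, covariates, the rule for named peaks and most alternatives were fixed before the data were examined. Total counts in peaks were 7733254 to 22020858 per forewing library and 6977525 to 14795457 per hindwing library. The median interval held 7 counts per library in both tables, so that changes of weakly covered peaks were measured with low precision.

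Changes between stages were tested within each wing with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, data.table version 1.17.8). Library sizes were scaled by TMM factors (0.734 to 1.366), peaks were kept by filterByExpr (minimum count 10, minimum total 15), and all 4 stages of a wing shared one estimate of spread. All adjusted p-values of peaks are from these tests with Benjamini-Hochberg adjustment over tested peaks, and a peak was called at an adjusted p under 0.05. A joint test covered the 4 stages, and contrasts covered the 3 steps between successively labelled stages. CPM values are TMM-normalized, except in the library correlations and for peaks without overlap in the other table, which use library totals. Standard errors of log2 changes come from the same fits.

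The wing tables shared 99 intervals with identical coordinates. Intervals were therefore matched as best pairs with a reciprocal overlap of at least 80%, which gave 136423 pairs, of which 127816 were tested. Wing differences per stage, their mean over stages and the interaction of wing and stage were tested in one fit of all 24 libraries. Since matched intervals need not have the same ends, an offset for the ratio of their widths was tried after seeing the data. Peaks of one table without any overlap in the other entered no wing test. Windows of 100 kb with at least 5 tested peaks were tested for an excess of called peaks by one-sided Fisher's exact tests against all tested peaks, with Benjamini-Hochberg adjustment over windows; neighbouring peaks are not independent, so those p-values are too small to be read as exact probabilities for a window.

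For each step and for the mean wing difference, the rule for named peaks took the 3 rising and the 3 falling peaks with the largest log2 change among called peaks with at least 5 CPM in the higher group and no overlap between the libraries compared (under each stage label for the mean difference). For each wing comparison within a stage it took 1 peak in each direction, and for the windows the 3 with the lowest adjusted p. The text prints some of these; further items are said to be chosen after their values were seen. Folds against groups without reads use a floor of 3 counts over the group, and ratios to groups of 1 to 3 counts have 95% counting intervals.

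The count tests were tested on simulated data: counts of 20000 peaks were drawn from the real means and library sizes, with 100 peaks changed 2-fold and 100 changed 4-fold. Of the 4-fold changes 66%, 71% and 64% were recovered for the successive forewing steps, 60%, 58% and 66% for the hindwing steps, and 61%, 72%, 63% and 64% for the wing differences at the 5th instar, prepupa, 72 h and 6 d. Of the 2-fold changes 3% to 16% were recovered in those comparisons. For the mean wing difference the shares were 78% at 2-fold and 100% at 4-fold, for the interaction 1% and 40%, and for the joint stage tests 16% and 80% in the forewing and 13% and 69% in the hindwing. False calls made up more than 5% of the simulated calls in some tests. The shares were 9.1% for the wing difference at prepupa and 5.2% for the hindwing step from 72 h to 6 d. For the joint stage tests they were 7.9% in the hindwing and 5.9% in the forewing. The simulated spread followed the fitted trend without a spread specific to each peak, so recovery in the real data may be lower. Recovery under the adjustment also depends on the share of changed peaks. The real stage steps called 5.2% to 34.9% of peaks, more than were changed in the simulation, which may raise recovery there. The 5th-instar wing comparison called 10 of 127816, which may lower it. Window tests recovered 100% of 20 planted windows and called 2 others.

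Whether replicate numbers pair the libraries was checked by correlating the deviations of same-numbered libraries from their group means over 40906 peaks; the labels name no shared animal, so the pairing comes from the data. Forewing and hindwing libraries of the 5th instar deviated together, each of the 3 pairs having a correlation of 0.39 or more. So did same-numbered libraries of the wings under 3 pairs of different labels: forewing prepupa and hindwing 6 d (0.295 to 0.409), forewing 72 h and hindwing prepupa (0.348 to 0.571), and forewing 6 d and hindwing 72 h (0.528 to 0.679). Same-numbered libraries of different stages within a wing had mean correlations from -0.076 to 0.106, and those of the wings under the same later stage label from -0.037 to 0.024. In wing comparisons the block joined libraries of the same number and stage label, so it did not model the pairing across different labels.

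Alternatives were RLE factors, no composition factors, loess offsets, no low-count filter, a filter of at least 50 counts in 3 libraries, DESeq2 1.42.0, the replicate number as a block, a minimum change of 2-fold, only the compared stages in the fit, overlaps of 50% and 95%, smaller and larger windows, and leaving out each library in turn. Added after seeing the data were the width offset, thinning of libraries to the smallest total of their wing and joint tests without the libraries labelled prepupa. Other splits of the libraries were tested on a fixed random subset of 10000 peaks. Correlations, components and window tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. Gene lists and motif content of peaks were not analysed here, because no genome or annotation of the build of the tables was used.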

Results

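Open chromatin was profiled by ATAC-seq in whole wing tissue of the buckeye butterfly Junonia coenia, reared at about 27 °C. In this assay a transposase inserts sequencing adapters into accessible DNA, so that the read count of an interval measures how open its chromatin is. Forewings and hindwings were sampled at 4 labelled stages: the 5th (last) larval instar, the prepupa, the pupa at 72 h and the pupa at 6 d, a group whose sample titles say day 7. Each of the 8 groups held 3 libraries, 24 in all. Read counts were given for 500558 forewing peaks on 964 contigs and for 488675 hindwing peaks on 959 contigs, with median widths of 122 bp and 137 bp. Total counts in peaks lay between 7733254 and 22020858 per forewing library and between 6977525 and 14795457 per hindwing library. The forewing libraries labelled 72 h (15551931 or more) and the hindwing libraries labelled prepupa (11955504 or more) were the deepest groups of their wing. The genome build behind the contig coordinates is not given in the sources used here and no annotation was used, so peaks are given by contig, start and end and are not placed in genes.

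Forewing libraries of one group resembled each other more than libraries of different groups, whereas in the hindwing the ranges overlapped. Peaks with at least 1 CPM were used, which is here the read count scaled to the library total without TMM factors. Spearman correlations of same-group libraries were 0.75 to 0.861 in the forewing and 0.68 to 0.832 in the hindwing. For libraries of different groups they were 0.375 to 0.687 and 0.38 to 0.704. The widest spread was among the hindwing libraries labelled prepupa (0.68 to 0.832), where replicate 2 stood at 0.04 on the first principal component and the other 2 at -0.28 and -0.36. Within groups no pair of replicates agreed within sampling noise, the chi-square per peak being 2.19 to 8.72 over 148527 to 315654 peaks. For same-numbered libraries across the wings, measured over other and fewer peaks (23748 to 29548 matched intervals overlapping by 95%), it was 1.8 to 1.94 for forewing prepupa and hindwing 6 d, 1.8 to 1.96 for forewing 6 d and hindwing 72 h, 2.63 to 3.02 for the 5th-instar wings, and 6.42 to 12.92 for forewing 72 h and hindwing prepupa. The last of these matches was not uniform over the replicates. For forewing 72 h and hindwing prepupa, replicates 1, 2 and 3 had 11.09, 6.42 and 12.92. For the wings that share the prepupa label they had 8.29, 22.2 and 8.68, lower for replicates 1 and 3. All 24 libraries were kept as separate samples. The share of counts taken by the top 1% of peaks was 15.9% to 17.1% in the hindwing group labelled 6 d and 16.8% to 19.0% in the forewing group labelled prepupa. It was 30.1% to 32.3% in the hindwing group labelled 72 h and 31.1% to 33.3% in the forewing group labelled 6 d.

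Stage profiles with the same name did not line up between the wings after the 5th instar. Across 131235 matched peaks, with each wing's mean over stages removed, the 5th-instar hindwing profile was closest to the forewing profile of the same name (Pearson r = 0.842). The hindwing group labelled 6 d was closest to the forewing group labelled prepupa (r = 0.915), whereas its correlation with the forewing group labelled 6 d was -0.527. Hindwing libraries labelled 72 h were closest to forewing libraries labelled 6 d (r = 0.89; same name, -0.279), and those labelled prepupa to forewing libraries labelled 72 h (r = 0.521; same name, 0.191). These correlations are across peaks, which are not independent replicates. The closest library in the other wing carried the same stage label for 7 of 24 libraries and the same replicate number for 21. Every forewing library labelled 72 h was closest to hindwing prepupa replicate 2, whereas hindwing prepupa replicate 3 was closest to forewing prepupa replicate 1. Stage names are used below as the labels give them, no library was moved to another group, and every wing comparison after the 5th instar rests on these names. So do the steps within a wing. If stage names differ between the tables, steps of the forewing, the hindwing or both do not join successive stages. Rises and falls below are therefore differences between labelled groups, and their order in development is not established.

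**Figure D1:**
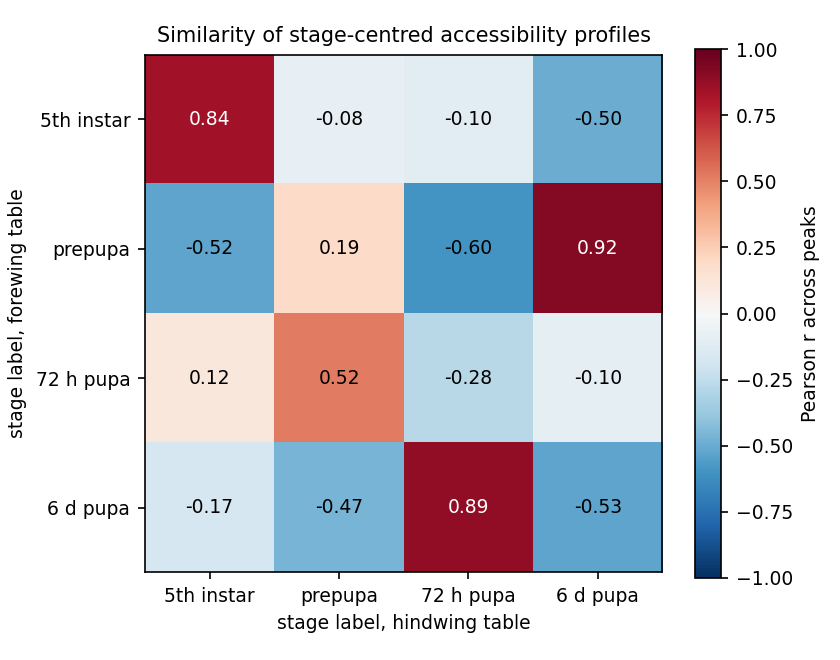
Pearson correlation across 131235 matched peaks between the stage-centred forewing profiles (rows, stage label) and hindwing profiles (columns, stage label), each the mean of 3 libraries; the colour scale runs from -1 to 1. Only the 5th-instar pair has its highest value on the diagonal (0.842), and the value of 0.915 lies between forewing prepupa and hindwing 6 d.

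The forewing landscape changed over the 4 labelled stages at 134102 of 253438 tested peaks (52.9%), and the hindwing landscape at 101137 of 258640 (39.1%; edgeR joint tests, adjusted p under the threshold of 0.05). Among the changing forewing peaks, 33.7% were most open in the libraries labelled 6 d, 25.3% at prepupa, 21.4% at the 5th instar and 19.6% at 72 h. In the hindwing 42.0% were most open at 72 h, 25.5% at 6 d, 21.6% at the 5th instar and 10.9% at prepupa. With library totals alone as the scale, without factors for composition, these shares became 49.6% for forewing prepupa and 19.4% for forewing 6 d, 15.4% for the forewing 5th instar, 47.1% for hindwing 6 d, 19.7% for hindwing 72 h, 18.0% for hindwing prepupa and 15.2% for the hindwing 5th instar. Without the libraries labelled prepupa, an alternative chosen after seeing the data, the joint tests called 75549 forewing and 97086 hindwing peaks.

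From the 5th instar to the libraries labelled prepupa, forewing chromatin closed at more of the tested peaks than it opened. Accessibility fell at 51151 peaks and rose at 28519 of 253438, with median log2 changes of -1.96 and 1.46, and the fall was at least 8-fold at 11473 peaks against 1406 rises of that size. At contig 000647F, 3831 to 4238, the mean was 21.2 ± 6.49 CPM (SD, n = 3) at the 5th instar and no read was counted in the 3 prepupa libraries, at least 229-fold lower (adjusted p = 1.83e-09); floors for groups without reads are 3 counts over the group. Contig 000029F, 1215955 to 1216718, had no read at the 5th instar and 9.13 ± 1.11 CPM at prepupa, at least 66.4-fold higher (adjusted p = 4.81e-08). Of 4897 windows of 100 kb, 611 were enriched for falling and 627 for rising peaks. The lowest adjusted p values were on contig 000219F, where 58 of 66 tested peaks between 400001 and 500000 fell with a median log2 change of -3.46 (one-sided Fisher's exact test, adjusted p = 2.28e-28), and on contig 000213F, where 59 of 97 between the same positions rose (adjusted p = 7.63e-28).

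Libraries of those groups did not overlap at 46.1% of tested forewing peaks, where chance gives 10%. With no composition factors the median of all peaks lay at 0.50 and the direction turned, with 68231 peaks rising and 34023 falling. Among peaks with at least 50 counts in 3 libraries the split was nearly even, 18881 rising and 19097 falling. All 6 peaks named by the rule for this step, and 25 of 45 over all comparisons, had no reads in one of the groups; tested peaks within 1 kb of such loci were lower in the same group by a median log2 change of -2.22, and counting intervals and floors cover counting error only.

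Between the forewing libraries labelled prepupa and 72 h the balance was the opposite: 45659 peaks rose and 17708 fell, with median log2 changes of 1.98 and -1.23. The interval at 000647F, 3831 to 4238, had 22.6 ± 2.87 CPM (n = 3) in the libraries labelled 72 h, at least 238-fold above those labelled prepupa (edgeR, adjusted p = 1.74e-09). Contig 000180F, 59095 to 59256, had 7.54 ± 1.15 CPM in the libraries labelled prepupa and no reads in those labelled 72 h, at least 124-fold lower (edgeR, adjusted p = 4.19e-08). Windows enriched for rising peaks numbered 695 and for falling peaks 451 of 4897. On contig 000241F, 74 of 78 tested peaks between 300001 and 400000 rose, with a median log2 change of 3.65 (exact test, adjusted p = 2.51e-46). The windows of 000219F that had closed rose at 62 of 66 and 65 of 71 peaks (adjusted p = 3.68e-38 for both); the steps before and after share the 3 prepupa libraries. Groups did not overlap at 45.7% of peaks (10% by chance). With no composition factors the median moved to -0.46 and the split turned to 32532 rising and 57363 falling. With at least 50 counts in 3 libraries it was 18474 and 16543.

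From 72 h to 6 d, forewing openings and closings were closer in number, with 36728 rising and 33180 falling peaks and median log2 changes of 1.53 and -1.76. Contig 000405F, 46009 to 46356, rose from 0.959 ± 0.675 to 47.1 ± 6.27 CPM (n = 3), a log2 change of 5.62 with a standard error of 0.44 (adjusted p = 1.66e-08). Contig 000190F, 915996 to 916512, fell from 14.7 ± 2.26 CPM to a single read over the 3 libraries labelled 6 d, a ratio of 304 with a 95% counting interval of 54.4 to 12000 (adjusted p = 9.45e-09). Of 4897 windows 423 were enriched for rising and 556 for falling peaks, led by 000238F, 500001 to 600000, for rising (46 of 66, adjusted p = 2.36e-20) and 000003F, 5400001 to 5500000, for falling peaks (72 of 112, adjusted p = 1.27e-32; exact tests). Groups did not overlap at 42.8% of peaks, against 10% by chance. With no composition factors the median lay at -0.25, and 27224 peaks rose and 44382 fell. The balance also turned with no low-count filter (36919 rising and 38901 falling), without 72 h replicate 1 (26427 and 27165) and without 72 h replicate 3 (27273 and 28071).

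In the hindwing, the step from the 5th instar to the libraries labelled prepupa had the fewest calls of the 6 steps: 3800 peaks rose and 9751 fell among 258640, with median log2 changes of 1.81 and -1.62. A peak at contig 000219F, 67006 to 68414, rose from 0.295 ± 0.305 to 17.3 ± 12.9 CPM (n = 3; log2 change 5.86, SE 0.83, adjusted p = 0.000246). Contig 000054F, 328332 to 328685, fell from 14.4 ± 9.72 CPM to 2 reads over the prepupa group, a ratio of 299 (95% counting interval 82 to 2480; adjusted p = 0.000127). Enriched windows numbered 96 for rising and 170 for falling peaks of 4903. Among them, 26 of 66 peaks rose on 000059F between 600001 and 700000 (exact test, adjusted p = 9.23e-27), and 24 of 82 fell on 000054F between 400001 and 500000 (exact test, adjusted p = 1.25e-11). The count of calls depended on single libraries: without prepupa replicate 2 it was 25188, and it was 5860 without prepupa replicate 1, 6437 without prepupa replicate 3, 5758 without 5th-instar replicate 2 and 5408 without 5th-instar replicate 3. Without composition factors the median lay at 0.39 with 10851 rising and 7647 falling peaks, with loess offsets 6579 rose and 9539 fell, with at least 50 counts in 3 libraries 7831 rose and 8455 fell, and groups did not overlap at 24.7% of peaks (10% by chance).

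Between the hindwing libraries labelled prepupa and 72 h, 33430 peaks rose and 20055 fell, with median log2 changes of 1.74 and -1.65. The strongest signal among the named peaks was at contig 000114F, 1397733 to 1398221, which rose from 2.49 ± 0.706 to 132 ± 13.5 CPM (n = 3; log2 change 5.73, SE 0.39, adjusted p = 7.47e-08). Contig 000012F, 444123 to 444984, fell from 11.2 ± 7.57 to 0.329 ± 0.328 CPM (log2 change -5.10, SE 0.67, adjusted p = 1.42e-05). Of 4903 windows 295 were enriched for rising and 365 for falling peaks. The window of 000238F from 500001 to 600000, which rose from 72 h to 6 d in the forewing, rose at this step in the hindwing at 42 of 65 peaks, while 48 of 96 peaks fell on 000072F from 1800001 to 1900000 (exact tests, adjusted p = 1.18e-18 and 3.37e-24). Without prepupa replicate 1 the step had 35581 calls and without prepupa replicate 3 it had 35212, against 53485 with all libraries. The median of all peaks was -0.13; with no composition factors it was -0.66, with 20302 rising and 62784 falling. With at least 50 counts in 3 libraries 15712 rose and 15845 fell, and groups did not overlap at 36.3% of peaks (10% by chance).

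With the main filter the hindwing step from 72 h to 6 d had the most calls, with 54072 peaks falling and 36126 rising. Falls of at least 8-fold numbered 12710 against 3249 such rises. Contig 000050F, 1567678 to 1568216, fell from 72.4 ± 9.14 CPM (n = 3) to no reads, at least 649-fold lower (adjusted p = 8.39e-08). The interval at 000647F, 3849 to 4235, fell from 38.0 ± 5.69 CPM to no reads, at least 342-fold lower (adjusted p = 8.95e-08). Contig 000333F, 352803 to 353457, had no reads at 72 h and 10.7 ± 1.31 CPM at 6 d, at least 69.4-fold higher (adjusted p = 4.13e-06). Windows enriched for falling peaks numbered 586 and for rising peaks 720 of 4903. All 28 tested peaks of 000414F between 200001 and 300000 fell, with a median log2 change of -6.13, and 66 of 98 rose on 000214F between 600001 and 700000 (exact tests, adjusted p = 4.53e-16 and 1.03e-29). Groups did not overlap at 47.9% of peaks (10% by chance), and without composition factors the median lay at 0.69 with 85253 rising and 32399 falling. With at least 50 counts in 3 libraries 15538 rose and 18847 fell, and these 34385 calls were fewer than those of each forewing step.

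**Figure D2:**
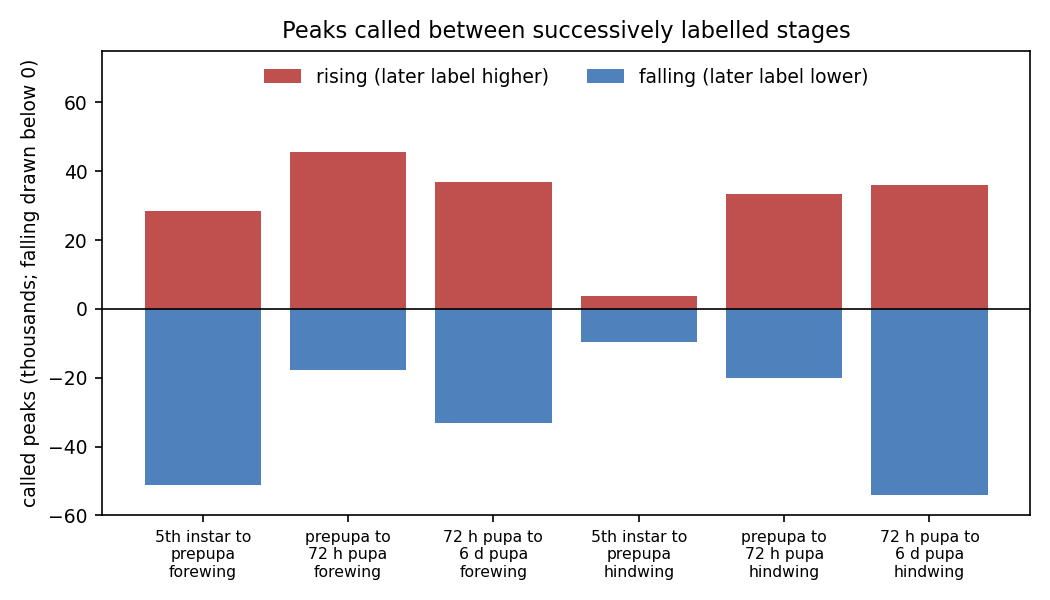
Number of called peaks (in units of 1000) for each of the 6 comparisons of successively labelled stages, rising peaks drawn above 0 and falling peaks below it. The hindwing step from 5th instar to prepupa has the shortest bars (3800 and 9751 peaks), and the hindwing step from 72 h to 6 d the longest falling bar (54072).

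With the stage labels as given, the stage changes of the wings correlated positively at the first step and negatively at the last. Over 113371 matched peaks the log2 changes from 5th instar to prepupa correlated at r = 0.63 (Spearman 0.64), and 99% of the 6588 peaks called in both wings moved the same way. From prepupa to 72 h the correlation was 0.23 (Spearman 0.29), with 72.5% of 9970 peaks in the same direction. From 72 h to 6 d it was -0.59 (Spearman -0.66), and 2.7% of 23244 shared peaks moved the same way. The forewing group labelled 6 d was closest to the hindwing group labelled 72 h (r = 0.89), and these groups enter the last step with opposite signs. The first step starts from the 5th-instar groups, which lined up (r = 0.842), whereas the prepupa groups correlated at 0.191. These values therefore depend on the stage names and are not read as likeness or difference between the wings. Independent lists would have shared 2786, 7340 and 14884 peaks, and the correlations are across peaks. Restricted to peaks with at least 50 counts in 3 libraries, the correlation of the middle step was 0.08, and over peaks called in either wing it was 0.14.

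Few peaks were called different between forewing and hindwing in the 5th instar, the stage at which the profiles of both tables lined up. In simulated data this comparison recovered 7% of 2-fold and 61% of 4-fold changes. The low count therefore does not show that few peaks differ. Of 127816 matched peaks, 10 were called, 7 more open in the hindwing and 3 in the forewing. Contig 000025F, 975305 to 975639, had 31.6 ± 3.39 CPM in the hindwing and 2.33 ± 0.519 in the forewing (n = 3 each; log2 difference 3.74, SE 0.49, adjusted p = 0.00225). In the opposite direction, contig 000027F, 519687 to 519980, had 15.6 ± 2.55 CPM in the forewing and 2.08 ± 0.992 in the hindwing (log2 difference -2.87, SE 0.39, adjusted p = 0.00261). Of the 7 hindwing peaks 4 lay on contig 000025F, and its window from 900001 to 1000000 held 3 calls among 28 tested peaks (exact test, adjusted p = 5e-06). Replicate numbers paired the wings at this stage (as they did between some groups with different stage labels), and with the replicate number as a block 3 peaks were called, all among the 10. The unadjusted p was under 0.05 at 6199 peaks (4.85%), and loess offsets called 11 hindwing and 9 forewing peaks. The split was 28 hindwing and 30 forewing peaks with DESeq2, 14 and 13 with at least 50 counts in 3 libraries, 3 and 3 with an offset for interval widths, 0 and 1 with matching at 95% overlap, and 333 and 517 (850 in all) at 50% overlap. Without forewing replicate 2 or 3 the edgeR count was 4 each, without hindwing replicate 2 it was 3 and without hindwing replicate 3 it was 5.

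Averaged over the 4 stage labels, which does not depend on how the stage names are placed within a wing, 59 of 127816 matched peaks differed between the wings, 45 more open in the forewing and 14 in the hindwing. Contig 000035F, 1506189 to 1507973, was the only one of them without overlap between the wings under every stage label, with 37.3 ± 6.16 CPM in the forewing and 18.9 ± 8.86 in the hindwing (n = 12 each; log2 difference -1.10, SE 0.11, adjusted p = 2.86e-05). Of the 14 hindwing-higher peaks 8 lay within 148325 bp of contig 000025F, from 951110 to 1099434, a run singled out after its values were seen. Within that run 39 peaks were tested, none was called higher in the forewing, and 93.5% of those not called lay above 0, with a median log2 difference of 0.49 (quartiles 0.35 and 0.69); at the 5th instar that median was 0.69. The shift was not confined to the run: of 38 tested peaks within 50 kb on either side, none of them called, 86.8% lay above 0 with a median of 0.36 (71.1% and 0.22 at the 5th instar). The windows of this contig from 1000001 to 1100000 (5 of 31 called, adjusted p = 1.31e-08) and from 900001 to 1000000 (3 of 28, adjusted p = 0.000673) were the only 2 of 4433 enriched for such calls by the exact test.

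The number of peaks in the averaged comparison was unsteady: it was 1595 without hindwing prepupa replicate 2, and 18 without hindwing replicate 1 of the 6 d group. Only 8 peaks were called, 1 of them higher in the hindwing, when the ratio of interval widths was an offset, an alternative chosen after seeing the data. The count was 17244 (7472 of them hindwing-higher) when peaks were matched at 50% overlap in place of 80%, and at 95% overlap none of the 4 peaks tested in the 000025F run was called.

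**Figure D3:**
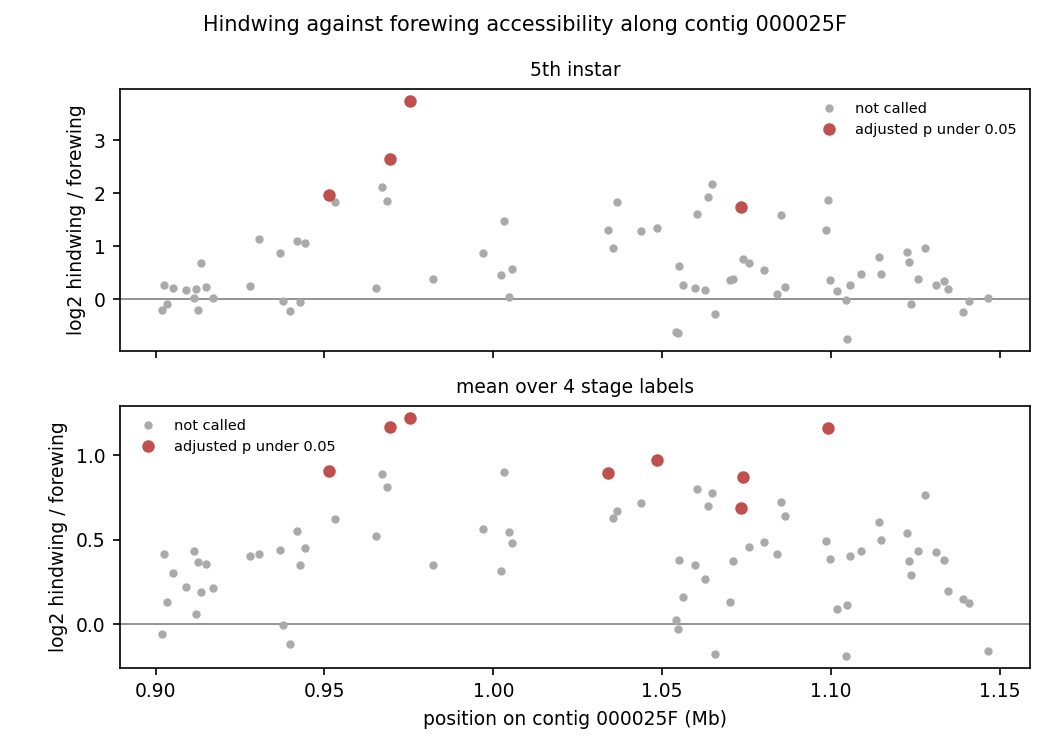
Log2 ratio of hindwing to forewing accessibility against position (Mb) on contig 000025F, in the 5th instar (top) and averaged over 4 stage labels (bottom); each point is a tested matched peak and red points are called. Points between 0.95 and 1.10 Mb lie mostly above 0, with 4 called in the 5th instar and 8 in the average.

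For later stages the wing comparison, taken with the labels as they stand, gave counts that grew from label to label. At prepupa 11646 peaks were more open in the hindwing and 4565 in the forewing, at 72 h 19416 and 15228, and at 6 d 24177 and 33221. Contig 000647F, 3831 to 4238, had no reads in the forewing libraries labelled prepupa and 26.1 ± 15.9 CPM in the hindwing ones (n = 3), at least 135-fold higher (adjusted p = 1.45e-07). In the libraries labelled 6 d, contig 000050F, 1567688 to 1568218, had 106 ± 3.44 CPM in the forewing and no reads in the hindwing, at least 531-fold lower (adjusted p = 4.35e-11). At 72 h contig 000290F, 216838 to 216990, had 2 reads over the forewing group and 5.57 ± 3.05 CPM in the hindwing, a ratio of 73.2 (95% counting interval 19.5 to 616; adjusted p = 2.13e-05). With no composition factors the splits were 9160 hindwing-higher and 6510 forewing-higher at prepupa, 13432 and 24679 at 72 h (median -0.34) and 47154 and 20185 at 6 d (median 0.60). At prepupa they were 7036 and 4476 with at least 50 counts in 3 libraries, and the prepupa count was 9339 without forewing prepupa replicate 2 and 9551 without hindwing prepupa replicate 2. With these labels, stage changes differed between the wings at 66798 of 127816 peaks (52.3%, joint interaction test). The counts by step were 5018 at the first, 23619 at the middle one and 68280 at the last.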

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

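Of the tests in this part, those of presence or absence by replicate number, of neighbouring peaks, of replicates without reads and of the remaining peaks of the 000025F run were set out before their results were seen; the thinning, stage-order, same-number and column-order tests were chosen only after the result was seen.

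With the stage labels as given, stage changes differed between the wing tables at 66798 peaks jointly, by tests of the difference itself. By step the counts were 5018 from 5th instar to prepupa, 23619 from prepupa to 72 h and 68280 from 72 h to 6 d. Stage names displaced between the tables would give such differences too, so they are not read as differences between the wings. Data outside the wing comparisons also held signal: 117 forewing and 10 hindwing peaks without any overlap in the other table reached a group mean of 5 CPM. The highest were contig 000086F, 608583 to 609406, with 24.2 CPM in the forewing libraries labelled 72 h, and contig 000408F, 32290 to 32642, with 12.9 CPM in the hindwing libraries labelled prepupa.

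The stage profiles did not line up between the wing tables after the 5th instar. Depth is argued against, since with all libraries thinned to one total 1 of 4 hindwing groups had its closest forewing profile under the same name, and a shift in developmental timing, which keeps the order of stages, since the matched stages had 2 inversions. A wing difference in chromatin as the whole cause is argued against too: same-numbered libraries of the matched groups with different names deviated together with correlations of at least 0.295, against at most 0.129 under the same later name. A candidate explanation is that stage names of columns differ between the tables: at loci where some replicates had no reads and the others at least 20, the pattern by replicate number recurred between the forewing group labelled 6 d and the hindwing group labelled 72 h at 310 of 310 loci (100%), against 1 of 5 and 6 of 45 for the groups that share these names, and likewise at 32 of 32 loci for forewing 72 h and hindwing prepupa and at 15 of 15 for forewing prepupa and hindwing 6 d, where another numbering reached 86.7%. Which table would hold displaced names cannot be told apart here: named by the matching hindwing groups the forewing columns stand in developmental order, but chance gives this at a share of 0.167; wing differences beside displaced names stay open.

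A further pattern was loci without reads in a whole group and at least 5 CPM in another, 101 in the forewing libraries labelled prepupa and 194 in the hindwing libraries labelled 6 d, against 1 to 26 in the other groups. Sequence absent from some of the sampled animals may contribute: tested peaks within 1 kb of 171 such loci had a median log2 change of -2.22 in the group without reads. That median was -2.24 over 54 loci of the forewing group labelled prepupa. Over 85 loci of the hindwing group labelled 6 d the fall was smaller and varied more (median -1.93, quartiles -2.83 and -0.75). Loci with no reads in one replicate and at least 20 in another numbered 6395, 27.9 times the 229 in counts simulated from the fitted spread. That simulation followed the trend of the spread without a spread specific to each peak. Peaks more variable than the trend would therefore raise this ratio too, whatever their cause. A separate count took matched peaks at which some replicates had no reads and the others at least 20 in both 5th-instar wings. At 177 of 177 of these the same replicate numbers lacked reads. Closing of a whole neighbourhood would also lower the neighbours, so a stage difference in chromatin remains open for loci without reads in all 3 replicates.

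The run of hindwing-higher peaks on contig 000025F was weighed against a regional difference in copy number or mapping, which would raise every peak of the run alike. The median of the peaks not called was 0.49, between the bounds set for the test (above 0.5 if it were the cause, below 0.25 if not). That test therefore cannot tell this explanation from a wing difference in chromatin. Wings of the same animals would share copy number. At the 5th instar the same replicate numbers lacked reads in both wings at 177 of 177 loci, as such wings would. This argues against an inherited copy number difference at that stage. The labels name no shared animal, and a mapping difference stays open. The 38 tested peaks within 50 kb beside the run had a median of 0.36, so the shift was not confined to it. With the width offset 1 of its 8 calls passed the threshold; the median log2 difference of the 8 went from 0.94 to 0.82 with a median standard error of 0.15 in both fits, and adjusted p from 0.0049 to 0.049 without the offset to 0.0349 to 0.298 with it (edgeR). No edgeR setting called a peak of the run higher in the forewing.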

How the results depend on the processing

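The width offset, the thinned libraries and the fits without the libraries labelled prepupa were chosen after seeing the data. Under alternatives 179 values, most of them total counts of calls, stayed within 1.5 times a reported count, 5 percentage points of a share or 0.1 of a correlation, and 45 moved; this does not speak of the split into rising and falling peaks, which turned in several comparisons, as the report gives. All 45 values of named peaks kept their call and direction under every alternative in which they could be tested; on leaving out libraries 1 call was lost, that of contig 000037F, 1317371 to 1317787, from hindwing 5th instar to prepupa (adjusted p 0.0168 with all libraries), at adjusted p = 0.0776 without 5th-instar replicate 3, 0.0936 without prepupa replicate 1 and 0.0746 without prepupa replicate 3 (edgeR; range over its alternatives 0.00653 to 0.0936).

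Without composition factors 83086 peaks were called for hindwing prepupa to 72 h and 93 for the mean wing difference, and the shares most open were 15.4% (5th instar), 49.6% (prepupa) and 19.4% (6 d) in the forewing and 15.2%, 18.0%, 19.7% and 47.1% over the hindwing stages in order. With loess offsets the 5th-instar and mean wing differences had 20 and 126 calls. Without a filter the first forewing steps had 122960 and 103203 calls. With at least 50 counts in 3 libraries, where fewer peaks were tested, the forewing had 55514 calls jointly and 37978, 35017 and 34839 by step, the hindwing 44079 jointly and 31557 and 34385 for the last steps, the wings 27, 22180, 28476 and 223 (5th instar, 72 h, 6 d, mean) and the interaction 33207, and the correlation of the middle step was 0.08 (reported 0.23; 0.14 over peaks called in either wing). A minimum of 2-fold left 15 calls for the mean. At 50% overlap wing differences numbered 850, 35105, 58286 and 91627 by stage, 17244 for the mean and 107338 for the interaction. Matched pairs numbered 270388 there and 136423 at 80% overlap, so the mean count (59 at 80%) rose far more than the pairs. Widths of paired intervals can differ more at 50% overlap, and the width offset was not tried there. At 95%, with fewer pairs, the counts were 1, 5223, 12109, 17388, 9 and 19651. The width offset left 6 (5th instar) and 8 (mean). Without the libraries labelled prepupa the forewing joint test called 75549. DESeq2 called 58 at the 5th instar and 617 for the mean. The cause of these moves was not tested. With the replicate number and stage label as a block 3 peaks were called for the 5th-instar wings, which the numbers pair; no other count moved by 1.5 times, the mean having 53 and the joint tests 126102 and 94701. The numbers also paired libraries of the wings under different labels; this block does not hold that pairing, so its value for the mean is no test of a paired design.

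Leaving out each library in turn gave 64302 to 74587, 48586 to 57184 and 53592 to 67015 calls for the forewing steps, 5408 to 25188, 35212 to 59709 and 74704 to 88046 for the hindwing steps, 122937 to 144601 and 87428 to 113757 for the joint tests, 3 to 11, 9339 to 15880, 26398 to 31144 and 48331 to 53583 for the wing differences by stage, 18 to 1595 for the mean and 62208 to 68099 for the interaction. For the mean wing difference (59) the counts without replicates 1, 2 and 3 were 36, 36 and 34 for forewing 5th instar, 42, 28 and 30 for prepupa, 29, 20 and 47 for 72 h and 31, 29 and 50 for 6 d, and 34, 28 and 45, then 22, 1595 and 30, then 37, 32 and 36, then 18, 29 and 29 for the hindwing in the same order. Libraries that moved other counts are named in the report. Shares most open ranged from 19.2% to 22.5%, 20.8% to 27.0%, 17.8% to 21.4% and 30.5% to 35.3% in the forewing and 19.7% to 24.9%, 10.4% to 11.6%, 40.5% to 45.8% and 20.5% to 24.7% in the hindwing, stages in order. At the real totals and 3 libraries per group, 3% to 16% of simulated 2-fold step or stage-wise wing changes were recovered. This holds for the fitted trend of the spread and the simulated share of changed peaks. How much of it was due to depth was not tested. Thinning to the smallest total of the wing lowered the calls to 68000, 48776 and 57392 for the forewing steps and to 12801, 46539 and 77121 for the hindwing steps, each within 1.5 times the reported count.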

Other observations

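All tests of other splits in this part were chosen only after the result was seen; the window tests were planned.

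Further windows were enriched for calls in one direction. On contig 000015F, 3200001 to 3300000, 47 of 78 tested forewing peaks rose from 72 h to 6 d (adjusted p = 4.18e-17) and 48 of 69 hindwing peaks fell (adjusted p = 8.41e-15; one-sided Fisher's exact tests). The window of 000006F from 3200001 to 3300000 fell in the forewing from 72 h to 6 d at 69 of 104 peaks with a median log2 change of -2.26 (exact test, adjusted p = 1.27e-32), and rose in the hindwing from 5th instar to prepupa at 17 of 76 peaks with a median of 2.03 (exact test, adjusted p = 1.82e-12). On 000214F, 600001 to 700000, 42 of 98 hindwing peaks fell from prepupa to 72 h and 66 rose from 72 h to 6 d, with medians of -1.84 and 2.10; these steps share the 72 h libraries.

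Named peaks of the 5th-instar wing comparison beyond the rule, chosen after their values were seen, include contig 000041F, 296092 to 296548, with 25.02 ± 2.66 CPM in the hindwing and 5.45 ± 0.999 in the forewing (n = 3; log2 difference 2.19, edgeR adjusted p = 0.00225). Contig 000085F, 1243786 to 1244275, had 31.1 ± 8.02 CPM in the forewing and 10.02 ± 0.858 in the hindwing (n = 3; log2 difference -1.63, edgeR adjusted p = 0.0145).

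Calls were recounted among 10000 peaks for other splits of the same libraries. For the joint stage tests the real split gave 5261 forewing calls and 1 of 100 drawn splits, the real one, gave as many (highest other 961). In the hindwing it gave 3801 calls, again reached by 1 of 100 (highest other 2016). This argues against a chance split of these libraries, though 100 drawn splits cannot exclude it. It does not tell whether replicates are separate animals. The interaction of wing and stage gave 5283 calls, reached by 1 of 100 splits (highest other 1088). Its splits exchanged libraries between the wings within a stage label, and after the 5th instar groups of one label did not line up. The count can therefore reflect displaced stage names, and no conclusion on a wing-by-stage difference is drawn from it. For the mean wing difference chance was not excluded, since 6 of 100 splits gave at least its 5 calls. The interaction and the mean wing difference come from one fit. Neither that fit nor its splits keep the pairing by replicate number that the deviations showed across the wings. Neither result is therefore a test of a paired design. The highest other split for the mean wing difference gave 1130 calls, and what set it apart was not examined. Because these splits exchange libraries of groups with unlike profiles, they are no clean comparison for a wing effect.

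Splits of 3 libraries against 3 number 10, too few for a share under 0.05. The forewing steps gave 3048, 2348 and 2832 calls and the highest other split of each gave 0. The hindwing steps gave 501, 2008 and 3466, with highest others of 1, 0 and 0. Wing differences labelled prepupa, 72 h and 6 d gave 1406, 2662 and 4588 calls, with a highest other of 0. At the 5th instar the real split gave 2 calls and the highest other also 2, so that 2 of 10 splits gave as many. The 3 other splits that part all 3 same-numbered pairs there gave 0 calls each, and the split with 2 calls parts 1 pair.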
